A study of Mus musculus with 5 samples.

How the data were processed

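Single-cell RNA profiles of whole mammary gland were measured in 5 mice, 1 library per mouse, with 3 libraries labelled Frmd3 knockout and 2 labelled wild type (WT). They are called KO1, KO2, KO3, WT1 and WT2 by genotype label and replicate number. Cells were captured in droplets with the 10x Genomics 3′ kit, version 3, and sequenced on an Illumina NovaSeq in pairs of 150 bp, per the labels' protocols. The authors' Cell Ranger run gave raw UMI counts per gene and cell barcode, the unit of every value used here; the mm10 build is named per the submitters' processing notes. The deposited count matrices came from Cell Ranger 6.0.2 for KO1, KO2, WT1 and WT2 and from 6.1.2 for KO3, per the file headers. The annotation release and the rule that called barcodes as cells are not given in the sources used here. Every deposited barcode holds at least 500 UMIs, so shallower cells were not analysed here. The kit reads the 3′ end of transcripts, so a count says little about which exons a transcript holds.

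The matrices list 32285 genes, among them 40 duplicated symbols, and hold 32472 barcodes with 308558851 UMIs. Cells with at least 500 genes and at most 15% mitochondrial UMIs were kept, which left 28588. Doublets were scored in each library by comparing cells with simulated doublets, 2 per cell, and the top share, 0.8% per 1000 barcodes, was removed. That took out 1754 cells, with 916 from KO1, 209 from KO2, 61 from KO3, 230 from WT1 and 338 from WT2, and left 26834 cells. Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes, chosen without Frmd3 and without mitochondrial, ribosomal protein, haemoglobin and sex-linked genes, 30 principal components were taken. A graph of 20 nearest neighbours was clustered with the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), all libraries together and with no batch correction. A cluster was named "X-like" from marker lists fixed before the data were examined. It needed at least 3 markers detected in 10% of its cells and no other class ahead among its 10 leading genes; these thresholds were not among the choices made before the data were examined. Of the 35 clusters, 7 stayed unnamed. They held 41.9% of the cells of KO1, 6.89% of KO2, 3.02% of KO3, 5.98% of WT1 and 7.31% of WT2.

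Cells are not replicates, so UMI counts were summed per library and class, and each class was fitted alone over the libraries that held at least 20 of its cells. Classes with such sums in at least 2 libraries of each genotype were tested, 10 in all. The main test was edgeR 4.0.16 (filterByExpr, TMM normalization, robust quasi-likelihood fit) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 of knockout-labelled over WT. Each SE of a fold change is its absolute log2 value divided by the square root of edgeR's quasi-likelihood F statistic. It is not the spread between libraries. CPM values carry TMM factors unless stated, and those of Frmd3, Ifng and Hspa1a do not. Gene lists, 30 of pathways and 23 of cell type markers, were fixed before the data were examined. They were tested with limma 3.58.1 (camera on voom values, two-sided, preset correlation 0.01), adjusted over all lists with at least 3 measured members in a class. The same lists were also tested with an estimated correlation and with fry. Shares of cells were compared with two-sided exact permutation tests; 3 libraries against 2 give 10 splits and a smallest p of 0.1. Differences of the genotype effect between epithelial classes were tested in edgeR as an interaction with the library as a block. Floors for a gene at 0 stand for 3 UMIs in that library and cover counting error only.

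The rule for named genes was also fixed before the data were examined. It takes the genes with the largest change among those past the threshold, with library ranges that do not overlap and at least 20 CPM in the higher group, up to 10 per direction in each epithelial class and up to 4 in the others. Where fewer than 5 pass in an epithelial class, those with the smallest unadjusted p are added up to 5 per direction and given as values that did not pass. From each list that passed, and from both Notch lists, up to 4 members with the smallest unadjusted p may be named. Gene models without a name are counted only, and some genes that the rule takes are not reported here. Gene positions are on mm10, from GENCODE mouse release 21, matched by gene ID; it may not be the annotation the authors used.

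The fits were tested on simulated data with 200 genes changed per class. Of genes changed 4-fold, 90.8% were recovered in luminal progenitor-like cells, 67.7% in hormone-sensing luminal-like cells and 57.3% in basal/myoepithelial-like cells. Of genes changed 2-fold, 28% were recovered in the first of these classes, 10.3% in the second and 8.3% in the third. For the interaction test, 38.2% of 4-fold differences were recovered between luminal progenitor-like and hormone-sensing luminal-like cells. These rates hold for the simulated data only. In the real genotype fits of the same classes, 113 of 11465, 102 of 12831 and 65 of 8152 genes had an unadjusted p under 0.05. These counts lie below the share expected with no difference, so the real fits may recover fewer changed genes. The rates therefore cannot show that most 4-fold changes would have been found. The alternatives tried were DESeq2 1.42.0, other normalization and gene filters, a replicate block, each library left out in turn, doublets kept, looser and stricter cell filters, a finer clustering, equal numbers of cells and, for lists, the other set tests. Where leaving out a library left 1 in a genotype, that library was assumed to vary like the others. Python 3.11.15 with scipy 1.17.1, scikit-learn 1.9.0, numpy 2.4.6 and pandas 2.3.3 was used for the remaining steps.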

Results

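Mammary glands of mice labelled Frmd3 knockout were compared with those of WT mice by droplet single-cell RNA sequencing, which counts captured transcripts by unique molecular identifiers (UMIs). FRMD3 carries a FERM domain, a fold that links membrane proteins to the cytoskeleton. The series title ties the gene to tumor suppression, to the fate of mammary epithelial cells and to the Notch pathway. The 3 knockout-labelled libraries held 11040, 5619 and 3359 barcodes with 74947873, 66053067 and 24197344 UMIs, in the order KO1, KO2 and KO3. WT1 and WT2 held 5673 and 6781 barcodes with 55783468 and 87577099 UMIs. After filtering, 9450, 4440, 2218, 4831 and 5895 cells were used, in the order KO1, KO2, KO3, WT1 and WT2, and the same order holds for all lists of 5 values. Their median depths were 4178, 12913.5, 6739, 8634 and 12077 UMIs. KO3 had the lowest total and KO1 the lowest median depth of the cells used. In KO3, 18.5% of barcodes had more than 15% mitochondrial UMIs, against 3.80%, 13.2%, 6.33% and 6.39% in KO1, KO2, WT1 and WT2.

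Epithelial, stromal and immune cells were all present. Over all libraries together, fibroblast-like cells were the most numerous named class, with 2868, 1171, 973, 1685 and 2097 cells. In KO2, hormone-sensing luminal-like cells outnumbered them. The epithelium comprised luminal progenitor-like cells, led by genes such as Plet1, Aldh1a3, Lcn2, Wfdc18 and Csn3, hormone-sensing luminal-like cells, with Prlr, Areg and Ptn among their leading genes, and basal/myoepithelial-like cells, led by Krt14, Krt17, Cnn1, Krt5 and Acta2. These classes held 777, 404, 48, 749 and 283 cells, 295, 1633, 178, 637 and 1001 cells, and 129, 32, 37, 133 and 71 cells, respectively. Most hormone-sensing luminal-like cells of KO2 and WT2 lay in one cluster, with 1078 and 695 cells, in which KO1, KO3 and WT1 had 6, 3 and 15. One fibroblast-like cluster likewise held 726 and 1252 cells of KO2 and WT2 against 219, 222 and 98 of KO1, KO3 and WT1.

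Frmd3 itself was found at a similar low level under both labels. The gene lies on mm10 chromosome 4 at 74013442 to 74202214, on the plus strand. Over all barcodes it had 159, 202 and 44 UMIs in KO1, KO2 and KO3, or 2.12, 3.06 and 1.82 CPM. WT1 and WT2 had 79 and 210 UMIs, or 1.42 and 2.40 CPM. Most of these UMIs came from fibroblast-like cells, with 102, 57, 36, 67 and 41, and from Schwann/glial-like cells, with 1, 114, 1, 6 and 132. In fibroblast-like cells the log2 difference was 0.51 ± 0.46 (SE, n = 3 and 2; edgeR adjusted p = 0.9998), and without WT2 it was -0.022. In epithelial cells Frmd3 was at the limit of detection, with 1, 0, 1, 0 and 0 UMIs, where 3 UMIs would be 0.229, 0.0940, 0.409, 0.132 and 0.109 CPM, so no difference between genotypes was detectable there at this depth. The labels do not say which part of Frmd3 was deleted, and a 3′ tag outside the deleted part is still counted, so these values check nothing about the labels.

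**Figure D1:**
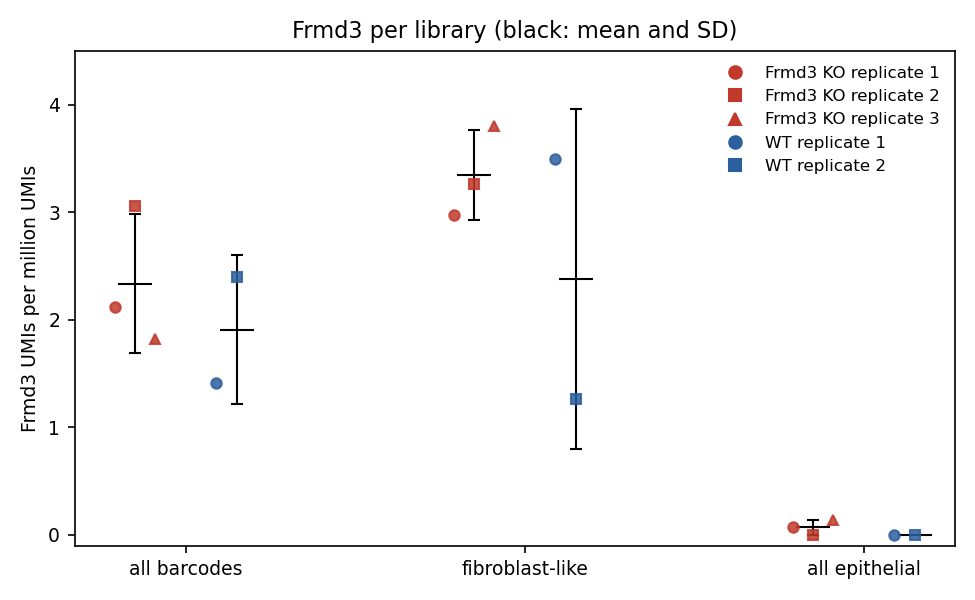
Frmd3 CPM (no TMM factors) in each library, over all barcodes, in fibroblast-like cells and in all epithelial cells; points are libraries, black bars the mean and SD (n = 3 knockout-labelled and 2 WT). The genotypes overlap in fibroblast-like cells, with 2.97, 3.26 and 3.80 in KO1, KO2 and KO3 against 3.49 and 1.26 in WT1 and WT2.

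To ask whether the makeup of the epithelium differed by genotype, the shares of its 3 classes were compared. Luminal progenitor-like cells made up 34.2% ± 26.5 (SD, n = 3) of epithelial cells in the knockout-labelled libraries and 35.1% ± 20.1 (SD, n = 2) in WT (exact permutation p = 0.9). Hormone-sensing luminal-like cells made up 57.1% ± 28.7 and 57.9% ± 22.6 (exact permutation p = 1.0), and basal/myoepithelial-like cells 8.79% ± 6.49 and 6.998% ± 2.49 (exact permutation p = 0.8). The differences were smaller than the spread between libraries. Luminal progenitor-like shares were 64.7%, 19.5%, 18.3%, 49.3% and 20.9%, so that KO2 lay close to WT2. Epithelial cells made up 12.7%, 46.6%, 11.9%, 31.4% and 22.99% of all cells (exact permutation p = 1.0).

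Among the other classes, natural killer (NK)/innate lymphoid-like cells were fewer in each knockout-labelled library than in either WT library. They made up 0.646%, 4.96% and 3.25% of cells in KO1, KO2 and KO3, a mean of 2.95% ± 2.17 (SD, n = 3). In WT1 and WT2 they made up 5.32% and 11.7%, a mean of 8.53% ± 4.54 (SD, n = 2). The exact permutation p was 0.1, the smallest this design allows, and 1.0 after adjustment over the classes; edgeR on the numbers of cells gave a log2 difference of -1.53 (adjusted p = 0.949). The difference of -5.58 percentage points was -2.37 without WT2 and -8.79 without WT1. Monocyte-like cells, with 0.275%, 1.64%, 1.22%, 2.65% and 2.14%, were also fewer in each knockout-labelled library (exact permutation p = 0.2, 1.0 after adjustment). With the looser cell filter they made up 1.43%, 2.50%, 4.68%, 5.89% and 4.02%, with KO3 above WT2 (exact permutation p = 0.3). They stayed fewer in each knockout-labelled library with the stricter filter, with doublets kept and with the finer clustering. T cell-like cells made up 4.13%, 1.94%, 3.47%, 4.14% and 6.07% (exact permutation p = 0.2), but over named cells alone, a choice made after seeing the data, 7.11%, 2.08%, 3.58%, 4.40% and 6.55%, with KO1 highest (exact permutation p = 0.6).

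**Figure D2:**
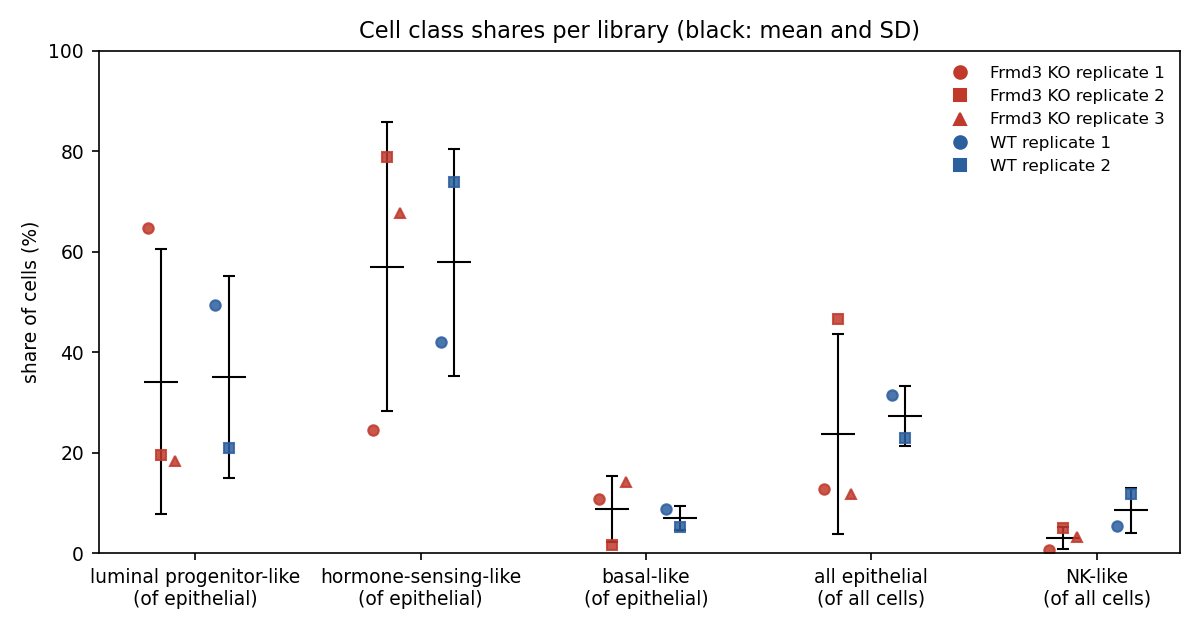
Shares of cell classes in each library, in percent of epithelial cells for 3 epithelial classes and in percent of all cells for all epithelial and NK/innate lymphoid-like cells; points are libraries, black bars the mean and SD (n = 3 knockout-labelled and 2 WT). The genotypes overlap in each class except NK/innate lymphoid-like cells, with 0.646% to 4.96% against 5.32% and 11.7%.

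In luminal progenitor-like cells, the lowest unadjusted p among lower genes in the knockout-labelled libraries fell to Acta1, a skeletal muscle actin, followed by interferon-inducible genes. Irgm1, an interferon-inducible GTPase, had 44, 34, 1, 203 and 69 UMIs (log2 -1.74 ± 0.37 SE). Gbp2, a guanylate-binding protein, had 9.43, 19.0, 8.92, 32.3 and 48.1 CPM (log2 -1.57 ± 0.34 SE). Nlrc5, the transactivator of MHC class I genes, and Oasl1 had log2 differences of -1.56 ± 0.37 and -1.37 ± 0.36 (SE). Among higher genes, Cdkn2b, an inhibitor of cyclin-dependent kinases, had a log2 difference of 2.01 ± 0.60 (SE) on 18, 28, 3, 7 and 6 UMIs. Wdr89 had 0.92 ± 0.24, Ahi1, a ciliary gene, 0.92 ± 0.28 and Mdm1 2.33 ± 0.63 (SE). Saa1, an acute-phase protein, had 15, 19, 0, 0 and 0 UMIs. None of these single genes passed. By edgeR 0 of 11465 genes were called, with 113 at an unadjusted p under 0.05, and DESeq2 called 0, with 66. With no difference at all, a share of 0.05 of the genes tested would be expected at such a p. The counts here lie below that share, as do those of every class and interaction given below, so they are not a sign of remaining differences. The library ranges of 1512 genes did not overlap between genotypes, where chance alone gives 20% of the genes tested. Without WT1 or without WT2, edgeR called 1 gene.

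As a group, interferon response genes were lower in luminal progenitor-like cells of the knockout-labelled libraries, in all 25 members measured, with a mean log2 difference of -0.87 (camera adjusted p = 6.6e-21). MHC class I genes, which present peptides to cytotoxic T cells, were lower in 14 of 14 members, with a mean of -1.11 (camera adjusted p = 1.6e-20). Both calls were lost with an estimated correlation (adjusted p = 0.463 for each). Adjusted over the list alone, edgeR called 1 interferon and 6 MHC class I genes. Ifi47, an interferon-inducible GTPase, had a log2 difference of -2.87 ± 0.79. H2-T22 had -0.91 ± 0.26, and Psmb9, a subunit of the immunoproteasome, -1.31 ± 0.39 (SE). Without WT1 the mean of the MHC class I list was -0.56 and that of the interferon list -0.55; the latter was -1.41 without KO2. Genes of leukocytes were also at lower levels in these cells: 8 pan-leukocyte genes summed to 35.1, 20.8, 13.7, 46.4 and 58.1 CPM without TMM factors. MHC class II genes were lower by a mean of -1.25 (camera adjusted p = 1.2e-06, and 0.463 with an estimated correlation) and dendritic cell markers by -0.88 (adjusted p = 0.0367, and 0.463).

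Of the 41 lists tested in luminal progenitor-like cells, 15 passed with the preset correlation, 5 higher and 10 lower, and 0 passed with an estimated correlation or with fry. Smooth muscle contraction genes were lower by a mean of -0.59 (camera adjusted p = 7.5e-05; 0.463 with an estimated correlation). Acta2, smooth muscle actin, had 8.20, 10.9, 4.46, 16.7 and 14.1 CPM. Basal/myoepithelial markers were lower by -0.72 (adjusted p = 5.2e-04; 0.463 estimated), with Krt14 at 3.14, 8.34, 0, 4.06 and 31.6 CPM. YAP/TEAD targets were lower by -0.29 (adjusted p = 0.00151; 0.463 estimated), among them Tead1 at -0.72 ± 0.48 and Ccn2, a matricellular protein, at -0.70 ± 0.54 (SE). Epithelial adhesion and tight junction genes were lower by -0.24 (adjusted p = 5.2e-04; 0.700 estimated). Basal transcription factors and basement membrane genes were lower by -0.19 (0.0248; 0.629) and hypoxia and glycolysis genes by -0.15 (0.0375; 0.551). NF-kB and inflammatory genes were higher by 0.73 (adjusted p = 0.00102; 0.485 estimated), with the chemokine Cxcl2 at 125, 294, 734, 59.5 and 149 CPM. Cell cycle, immediate-early and oxidative phosphorylation genes were higher by 0.36, 0.32 and 0.078 (adjusted p = 0.0401 each; 0.790 estimated).

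Heat shock genes were higher in all 13 members, by a mean of 1.26 (camera adjusted p = 5.9e-07; 0.553 with an estimated correlation). Most of that came from KO3: Hsph1, a chaperone, had 32.9, 56.9, 834, 28.4 and 31.2 CPM, and without KO3 the mean was 0.20 (adjusted p = 0.0086). Hspa1a and the near-identical Hspa1b share reads, so their split is uncertain. Over all cells used, Hspa1a had 139, 179, 1881, 149 and 103 CPM without TMM factors, again highest in KO3.

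In hormone-sensing luminal-like cells, Tead1, a transcription factor that acts with YAP, had 39.3, 38.3, 39.0, 61.7 and 57.8 CPM (log2 -0.62 ± 0.15 SE). Atf5, a stress-related transcription factor, had 19.3, 17.6, 20.4, 40.7 and 32.3 CPM (log2 -0.93 ± 0.19 SE). The leukocyte antigen gene Cd52 was at -2.05 ± 0.51, Arhgap45 at -2.54 ± 0.65, and St8sia4, a sialyltransferase, at -4.06 ± 0.95 on 1, 1, 0, 16 and 20 UMIs. Among higher genes, Slc5a8, a monocarboxylate transporter, had 5.55, 6.16, 15.1, 2.10 and 1.73 CPM (log2 2.21 ± 0.55 SE). Fggy was at 1.44 ± 0.38, Angpt1, an angiopoietin, at 1.29 ± 0.40, Fam129a at 1.20 ± 0.36 and Tceanc2 at 0.996 ± 0.278 (SE). None passed: edgeR called 0 of 12831 genes, with 102 at an unadjusted p under 0.05, and DESeq2 called 1, with 131. Library ranges did not overlap for 1455 genes, where chance gives 20% of those tested.

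Of 44 lists in hormone-sensing luminal-like cells, 16 passed with the preset correlation, 4 higher and 12 lower, and 0 with an estimated correlation or fry. MHC class II genes were lower by a mean of -1.05 (camera adjusted p = 3.8e-06; 0.426 estimated), with H2-Aa at 7.61, 3.24, 2.59, 18.5 and 10.2 CPM. Dendritic cell markers, which share H2-Ab1 and H2-Eb1 with that list, were lower by -1.13 (6.6e-05; 0.426). MHC class I genes were lower in 14 of 14 members, by -0.59 (adjusted p = 1.2e-05; 0.832 estimated). This mean was -0.059 without WT2 (adjusted p = 0.65), -0.35 without KO3, -0.94 without WT1 and -0.95 without KO2. In KO2 and WT2 set against the other libraries, the list was higher in 13 of 14 members, by 0.94 (camera adjusted p = 1.9e-06; 0.571 estimated). Collagens and matrix genes were lower in 24 of 25 members, by -0.80 (2.0e-04; 0.832), and fibroblast markers by -0.69 (0.0293; 0.832). Mesenchymal genes were lower by -0.43 (0.00993; 0.832), unfolded protein response genes by -0.30 (0.0477; 0.832), YAP/TEAD targets by -0.21 (0.0452; 0.832), and lipid synthesis and hypoxia genes by -0.16 each (0.0452 and 0.0210; 0.832). Adhesion genes were lower by -0.11 (0.0265; 0.832). The macrophage marker list passed as lower with a median of -0.22 and a mean of -0.025 (0.0261; 0.832).

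Among the 4 lists that passed as higher in hormone-sensing luminal-like cells, luminal progenitor markers had a mean of 1.85 (camera adjusted p = 0.00591; 0.832 estimated), but the receptor kinase gene Kit had 0.206, 3.00, 67.7, 0.935 and 2.50 CPM, Trf 5.14, 3.51, 155, 4.83 and 5.05, and Mfge8 35.6, 42.1, 385, 33.6 and 32.0. Milk and secretory genes had a mean of 1.88 (0.0308; 0.832) and share Trf and Mfge8. Heat shock genes were higher by 0.96 (6.3e-05; 0.832), and by 0.21 without KO3 (adjusted p = 0.0033). The cell cycle list was called higher (0.0361; 0.835 estimated) although its mean was -0.046 and its median -0.042. Without KO3, 8 lists passed in place of 16, with 2 higher and 6 lower.

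In basal/myoepithelial-like cells, H2-Q7, an MHC class I gene, had 3.63, 6.05, 3.20, 109 and 24.9 CPM (log2 -3.95 ± 0.76 SE). It shares reads with the near-identical H2-Q6, so its level is uncertain. DESeq2 called it (adjusted p = 0.0399) and edgeR did not. Ccl2, a chemokine that draws monocytes, had 73.9, 24.2, 17.6, 134 and 191 CPM (log2 -2.02 ± 0.55 SE). Kpna2, a nuclear import factor, was at -2.17 ± 0.61 and Serping1, the C1 inhibitor, at -2.41 ± 0.71 (SE). Among higher genes, Atp6v1d, a subunit of the vacuolar ATPase, had 52.1, 56.5, 79.9, 19.9 and 30.2 CPM (log2 1.31 ± 0.35 SE). Wdr89 was at 1.15 ± 0.32, Lncpint at 1.18 ± 0.38, Gfra2, a receptor for neurturin, at 1.64 ± 0.53, and Slc39a13, a zinc transporter, at 1.36 ± 0.45 (SE). None passed: edgeR called 0 of 8152 genes, with 65 at an unadjusted p under 0.05, and DESeq2 called 1, with 42. Library ranges did not overlap for 840 genes, where chance gives 20%. Without WT1 or WT2, edgeR called 8 genes each, and without KO1 it called 1.

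Of 37 lists in basal/myoepithelial-like cells, 7 passed with the preset correlation, 1 higher and 6 lower, and 0 with an estimated correlation or fry. MHC class I genes were lower in 12 of 12 members, by -1.04 (camera adjusted p = 4.1e-08; 0.967 estimated; 1 gene adjusted over the list alone). That mean was -0.32 without WT1 (adjusted p = 0.077) and -1.69 without WT2. Interferon response genes were lower in 13 of 13 members, by -0.73 (3.1e-06; 0.967), with -0.46 without WT1, -1.40 without WT2 and -1.21 without KO2. Cell cycle genes were lower by -0.42 (0.0118; 0.967) and proliferation markers by -0.95 (0.0124; 0.967), but Mki67 had 1.21, 68.6, 20.8, 8.30 and 137 CPM. Hypoxia and glycolysis genes were lower by -0.19 (0.0124; 0.967) and fibroblast markers by -0.99 (0.0216; 0.967). Heat shock genes were higher by 0.68 (5.8e-05; 0.967), and by 0.23 without KO3 (adjusted p = 0.12).

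Because the title names Notch signalling, both Notch lists were examined in each epithelial class. Neither passed in any class in the main fits, which hold no replicate block. Notch receptors, ligands and processing genes had a mean log2 difference of 0.036 over 20 genes in luminal progenitor-like cells, where the median was -0.023 and the test pointed lower (camera adjusted p = 0.689). In hormone-sensing luminal-like cells the mean over 21 genes was -0.0036, with a median of 0.0053 and a test pointing lower (adjusted p = 0.971). In basal/myoepithelial-like cells it was 0.071 over 21 genes (adjusted p = 0.767). Jag1, a Notch ligand, was at 1.06 ± 0.71 and Rbpj, the DNA-binding partner of Notch, at 0.28 ± 0.22 (SE) in luminal progenitor-like cells. Maml3, a coactivator, was at -0.39 ± 0.20 and Numb, an inhibitor of Notch, at -0.38 ± 0.22 in hormone-sensing luminal-like cells. In basal/myoepithelial-like cells Rfng, a glycosyltransferase that modifies Notch, was at 1.01 ± 0.54 and Notch1 at 0.43 ± 0.43.

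Notch target genes had means of -0.028 over 15 genes (camera adjusted p = 0.493), 0.20 over 13 (0.722) and 0.16 over 10 (0.719) in luminal progenitor-like, hormone-sensing luminal-like and basal/myoepithelial-like cells. In luminal progenitor-like cells, Nrarp, a feedback inhibitor induced by Notch, had 17.1, 36.4, 17.8, 28.4 and 76.0 CPM (log2 -1.04 ± 0.51 SE). Gata3, a luminal transcription factor, was at 0.47 ± 0.24 and Sox9 at -0.35 ± 0.25 (SE). Hey1 in hormone-sensing luminal-like cells was at 2.25 ± 1.47 and Cdkn1a at -0.46 ± 0.24, and Gata3 in basal/myoepithelial-like cells at 0.41 ± 0.31. In every epithelial class edgeR called 0 members of both lists, also adjusted over the list alone.

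Beyond the marker lists given above, luminal keratins and luminal transcription factors had a mean log2 difference of 0.10 in luminal progenitor-like, 0.43 in hormone-sensing luminal-like and 0.35 in basal/myoepithelial-like cells and did not pass (camera adjusted p = 0.586, 0.529 and 0.715). The markers of each class had means of -0.10, 0.050 and -0.11 within that class (adjusted p = 0.493, 0.882 and 0.241); for hormone-sensing luminal-like cells the median was -0.0030 and the test pointed lower. Wnt pathway genes had means of 0.033, 0.29 and -0.028 (0.689, 0.199 and 0.970), with a median of -0.072 and a test pointing lower in luminal progenitor-like cells and a median of 0.089 in basal/myoepithelial-like cells. Ovarian hormone response genes had means of 0.17, 0.12 and 0.57 (0.689, 0.226 and 0.7503), and genes of the FERM domain family -0.027, -0.048 and 0.012 (0.304, 0.499 and 0.767). Interferon response genes in hormone-sensing luminal-like cells had a mean of -0.21 and a median of -0.25 while the test pointed higher (0.838).

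The genotype effect did not differ detectably between epithelial classes. The edgeR interaction called 0 of 12604 genes between luminal progenitor-like and hormone-sensing luminal-like cells, with 97 at an unadjusted p under 0.05. Between luminal progenitor-like and basal/myoepithelial-like cells it called 0 of 10169, with 171. Between hormone-sensing luminal-like and basal/myoepithelial-like cells it called 0 of 12182, with 149. Without WT2 it called 3 genes for the first pair and 1 for the last, and without KO1 it called 1 for the second; no other tool was run.

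Single genes passed in 2 immune classes. In macrophage-like cells, Cxcl9, a chemokine induced by interferon gamma (chromosome 5 at 92321347 to 92328079), fell to 7.82, 11.3 and 9.25 CPM in KO1, KO2 and KO3 from 195 and 99.0 in WT1 and WT2. Its log2 difference was -4.01 ± 0.37 (SE, n = 3 and 2; edgeR adjusted p = 0.00632). Thbs1, the matrix protein thrombospondin 1 (chromosome 2 at 118111876 to 118127133), fell from 61.5 and 69.6 to 11.3, 11.3 and 7.93 CPM, with a log2 difference of -2.69 ± 0.31 (SE; edgeR adjusted p = 0.0207). Thbs1 is also among the leading genes of the monocyte-like cluster; monocyte markers in macrophage-like cells had a mean of -0.48 (camera adjusted p = 0.604). These were 2 of 8779 genes tested, with 169 at an unadjusted p under 0.05, and DESeq2 called 4, both among them. Without KO1 or without KO3, 0 genes passed; 7 passed without KO2, 8 without WT1 and 6 without WT2, with Cxcl9 in all of these and Thbs1 in all but the last.

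In B cell-like cells, Jchain, the joining chain of polymeric antibodies (chromosome 5 at 88519809 to 88527891), rose to 3350 and 2564 CPM in KO1 and KO2 from 913 and 849 in WT1 and WT2. KO3 had 0 B cell-like cells and was not in this fit. The log2 difference was 1.75 ± 0.20 (SE, n = 2 and 2; edgeR adjusted p = 0.0112), the 1 call among 7186 genes, also made by DESeq2. Jchain helps define this cluster, and plasma cell markers in it were higher by a mean of 0.91 (camera adjusted p = 0.00135; 0.600 with an estimated correlation). The count was 11 without KO1 and 37 without KO2, with Jchain in both, and 2 without WT1 and 0 without WT2, with Jchain in neither. No gene passed in the other 5 classes by edgeR: fibroblast-like, NK/innate lymphoid-like, T cell-like, dendritic cell-like and monocyte-like cells had 102, 158, 212, 123 and 116 genes at an unadjusted p under 0.05, and DESeq2 called 0, 0, 1, 0 and 0. Without WT2, edgeR called 51 genes in NK/innate lymphoid-like and 3 in T cell-like cells; without WT1 it called 6 in NK/innate lymphoid-like, 4 in dendritic cell-like and 1 in monocyte-like cells, and without KO1 it called 1 in dendritic cell-like cells.

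MHC class I genes were also lower outside the epithelium. In fibroblast-like cells they were lower in 14 of 14 members, by a mean of -1.19 (camera adjusted p = 1.3e-24; 0.444 with an estimated correlation), and 13 passed adjusted over the list alone. The mean was -0.69 in macrophage-like cells (1.7e-10; 0.688), -0.43 in dendritic cell-like cells (1.8e-06), -0.39 in T cell-like cells (2.6e-04), -0.23 in NK/innate lymphoid-like cells (0.00457), -0.22 in monocyte-like cells (0.0478) and -0.18 in B cell-like cells (0.0143). None of these passed with an estimated correlation. By the mean log2 CPM of the list in single libraries, the genotypes overlapped in 2 of these classes. In NK/innate lymphoid-like cells KO2 lay above WT2, at 8.40 against 8.38 (exact permutation p = 0.3). In B cell-like cells KO1 had 7.697 and KO2 8.098, against 8.102 and 8.086 in WT1 and WT2 (exact permutation p = 0.667). Other marker lists moved with the MHC class I genes in fibroblast-like cells. Erythroid markers were lower by -5.26 (camera adjusted p = 0.00114, and 0.508 estimated) and T cell markers by -1.80 (2.2e-05, and 0.444). In KO2 and WT2 against the other libraries, erythroid markers were lower there by -4.79 (camera adjusted p = 0.896). An unnamed cluster led by Hbb-bs and Hba-a1 held 1, 0, 0, 93 and 0 cells. For erythroid markers, a high level in WT1 alone cannot be told apart from a genotype difference. For single libraries, the mean log2 CPM of the list in luminal progenitor-like cells was 5.87, 6.51, 5.22, 7.53 and 6.63, a difference of -1.21 between genotypes (exact permutation p = 0.2).

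**Figure D3:**
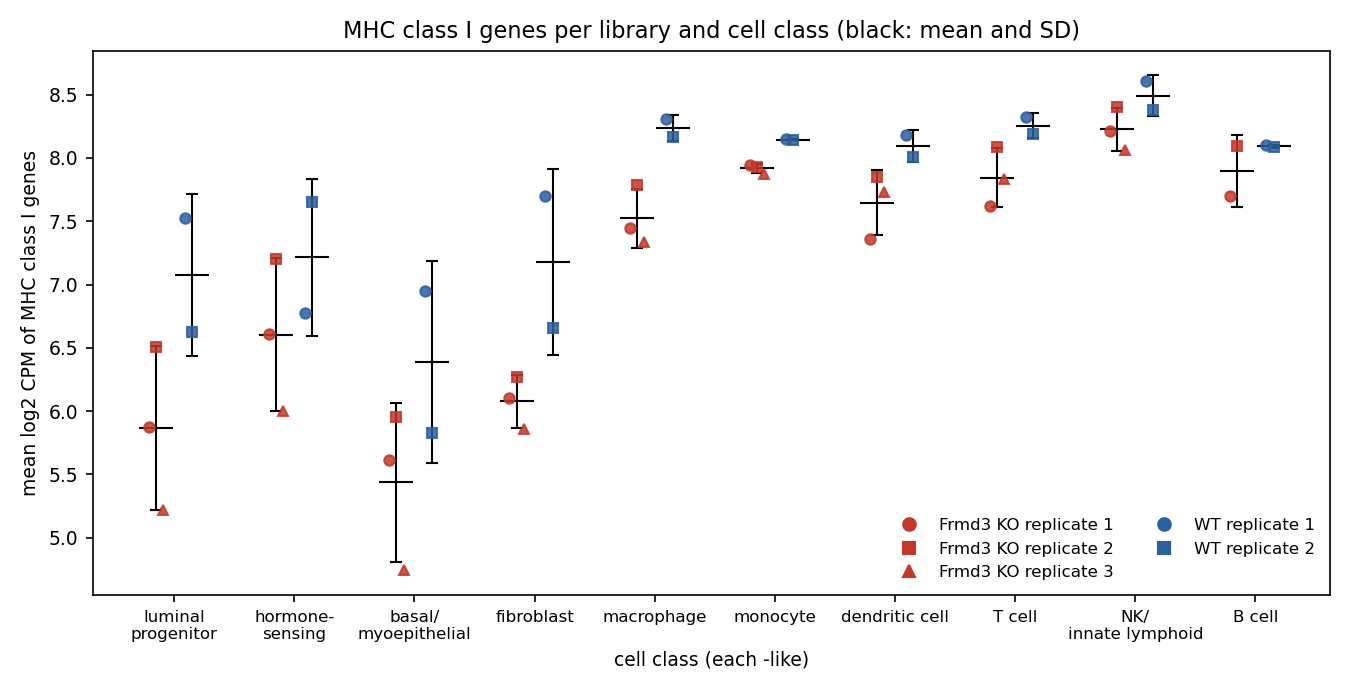
Mean log2 CPM of the MHC class I genes in each library and tested cell class; points are libraries, black bars the mean and SD (n = 3 knockout-labelled and 2 WT, and 2 and 2 in B cell-like cells). WT libraries lie above all knockout-labelled libraries in 6 of 10 classes, and in fibroblast-like cells they lie at 7.70 and 6.66 against 6.11, 6.27 and 5.86.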

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

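All tests in this part, and the shares of named cells, were chosen after the result was seen. A cluster that took no name held 3798 cells of KO1, which is 40.2% of the cells used from that library (exact binomial interval 39.2% to 41.2%, covering counting error only). It held 2, 0, 73 and 16 cells of KO2, KO3, WT1 and WT2, so the signal lay above its level in both WT libraries, in cells that no comparison of genes within a class uses. They do count in values over all barcodes or all cells used and in the shares of all cells: over named cells alone, the NK/innate lymphoid-like difference was -5.90 in place of -5.58 percentage points. Its leading genes were Retnla, Lyve1, Cd209f, Folr2 and Pf4, which tissue-resident macrophages express, yet macrophage markers took only 0.380% of its UMIs against 0.172% in the rest of KO1, and fibroblast markers took 2.61% against 3.00%. Droplets that caught 2 cells should hold more RNA than others, but the median was 2844.5 UMIs against 8611 in the named cells of KO1, a ratio of 0.330, which argues against that explanation. A candidate explanation is droplets filled with free RNA of the library: over genes, the summed profile correlated at 0.996 with the rest of KO1 and at 0.956 with fibroblast-like cells, the next highest; genes are not independent replicates. With the looser cell filter, 3687 of the 3798 cells joined the fibroblast-like class, which rose from 30.3% to 69.0% of KO1 and turned its share difference from -1.70 to 8.93 percentage points. Shallow fibroblast-like cells and damaged cells stay open, the latter with a median of 5.17% mitochondrial UMIs against 2.70%, and a difference tied to the genotype label was not tested, since KO2 and KO3 nearly lack such cells.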

How the results depend on the processing

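The fits with 2 blocks and the shares of named cells alone were chosen after seeing the data. Of 177 values under alternatives that keep all libraries, 127 kept their direction and side of the threshold, or their count within 1.5 times; of 184 values with 1 library left out, 135 did. The cause was not tested for any value below, except that untested low genes enter without a filter and fewer libraries enter when one is left out. The replicate numbers are shared by only 2 pairs and nothing says what they mark, so the main fits did not use them as a block. Libraries with the same number resembled each other in the values below, so a pairing stays open. The main fits count that likeness as spread between libraries. Deviations from the genotype means correlated at 0.253 and 0.425 for KO1 with WT1 and KO2 with WT2 in luminal progenitor-like cells. They correlated at 0.573 and 0.653 in hormone-sensing luminal-like, 0.586 and 0.422 in basal/myoepithelial-like and 0.428 and 0.669 in fibroblast-like cells. KO3 with WT1, which share no number, had 0.132, 0.016, -0.156 and 0.394 in the same order. With only WT1 and WT2, each value for WT1 is the exact opposite of that for WT2, so these values are not independent. With the replicate number as a block, KO3 is alone in its block, so the genotype term rests on KO1 and KO2 against WT1 and WT2. In these fits edgeR called 14 genes in luminal progenitor-like, 74 in hormone-sensing luminal-like, 12 in basal/myoepithelial-like and 4 in fibroblast-like cells. It called 15 in NK/innate lymphoid-like, 16 in monocyte-like, 7 in macrophage-like and 4 in B cell-like cells. Under this block 12 lists passed in basal/myoepithelial-like and 10 in hormone-sensing luminal-like cells, Notch targets in basal/myoepithelial-like cells reached a mean of 0.21 (camera adjusted p = 0.016), and Notch receptors in luminal progenitor-like cells turned to -0.040. Log2 share differences under the block were -0.69 for basal/myoepithelial-like and 0.15 for luminal progenitor-like cells.

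With 2 blocks, replicate 2 against the others, edgeR called 1 gene in basal/myoepithelial-like and 5 in macrophage-like cells, 11 lists passed in basal/myoepithelial-like cells, Notch targets there had a mean of 0.21 (camera adjusted p = 0.700), and in hormone-sensing luminal-like cells Notch receptors turned to 0.0014 and interferon genes to 0.036; it was not run for B cell-like cells. DESeq2 called 1 gene each in hormone-sensing luminal-like, basal/myoepithelial-like and T cell-like cells and 4 in macrophage-like cells. Without a filter on low counts, edgeR called 60 genes in luminal progenitor-like and 8 in basal/myoepithelial-like cells. With an estimated correlation or fry, 0 lists passed in any epithelial class. The hormone-sensing luminal-like share difference turned to 1.76 with the looser and 1.41 percentage points with the stricter cell filter, and the luminal progenitor-like one to 0.391 with doublets kept.

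With 1 library left out, in the order luminal progenitor-like, hormone-sensing luminal-like and basal/myoepithelial-like cells, share differences ranged from -16.2 to 13.3, -16.8 to 15.4 and -0.854 to 5.41 percentage points, and from -14.9 to 2.44 for all epithelial cells. Notch receptors ranged from -0.042 to 0.085, -0.063 to 0.046 and 0.018 to 0.16, Notch targets from -0.16 to 0.088, -0.091 to 0.47 and 0.018 to 0.41, MHC class I genes from -1.50 to -0.56, -0.95 to -0.059 and -1.69 to -0.32, and heat shock genes from 0.20 to 1.60, 0.21 to 1.21 and 0.23 to 0.90. Interferon genes ranged from -0.85 to 0.85 in hormone-sensing luminal-like cells, and Frmd3 in fibroblast-like cells from -0.022 to 1.30. From 16 to 21, 8 to 20 and 6 to 14 lists passed. Genes called ranged from 0 to 1 in luminal progenitor-like and monocyte-like, 0 to 8 in basal/myoepithelial-like and macrophage-like, 0 to 3 in T cell-like, 0 to 4 in dendritic cell-like, 0 to 51 in NK/innate lymphoid-like and 0 to 37 in B cell-like cells. Differences between classes ranged from 0 to 3 genes for luminal progenitor-like against hormone-sensing luminal-like cells and 0 to 1 for each of the other pairs. The smallest sum was that of KO3 in luminal progenitor-like cells, with 437845 UMIs from 48 cells, of KO1 in hormone-sensing luminal-like cells, with 4975933 UMIs, and of KO2 in basal/myoepithelial-like cells, with 489746 UMIs.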

Other observations

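The grouping by replicate number, the tests of explanations for the MHC class I genes, with their bounds, the split of T cell-like cells by cluster and the choice of 2210407C18Rik came after the results were seen; both tests of the replicate 2 pattern were set down before their values. Of the 10 splits of the libraries into 3 and 2, the one that sets KO2 and WT2 apart called 444 genes in luminal progenitor-like, 230 in hormone-sensing luminal-like, 119 in basal/myoepithelial-like and 630 in fibroblast-like cells by edgeR, where the genotype split called 0 in each. The split that sets KO1 and WT1 apart called 23, 73, 303 and 1. What the number marks is not given in the sources used here. In luminal progenitor-like cells, Apod, an apolipoprotein, had 848 and 630 CPM in KO2 and WT2 against 89.1, 152 and 115 in KO1, KO3 and WT1 (log2 2.69 ± 0.23 SE). Btn1a1, a protein of the milk fat globule, had 58.9 and 57.2 CPM against 192, 236 and 288 (log2 -2.04 ± 0.20 SE), and Stat5a, a transcription factor of prolactin signalling, and Hey1, a Notch target, were lower by -1.55 and -1.58. As a list, Notch target genes did not pass in this class and had a mean of 0.12 (camera adjusted p = 0.345). Milk and secretory genes were lower there by a mean of -0.88 (camera adjusted p = 1.8e-05, and 0.578 with an estimated correlation). Mitochondrial genome genes were lower with them in 13 of 13 members, by -0.74 (8.9e-11; 0.578), and immediate-early and dissociation genes by -0.68 (1.4e-06; 0.578). Macrophage markers were lower by -1.42 (0.0123, and 0.578) and fibroblast markers higher by 0.42 (0.0382, and 0.608). Hormone-sensing luminal markers were higher by 0.54 (0.0204, and 0.608) and proliferation markers by 0.96 (0.00946, and 0.578).

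In hormone-sensing luminal-like cells, Tph1, the enzyme that starts serotonin synthesis, had 2.46 and 2.41 CPM in KO2 and WT2 against 156, 159 and 94.1 in KO1, KO3 and WT1 (log2 -5.80 ± 0.33 SE, edgeR adjusted p = 0.00473), and interferon response genes were higher in 21 of 22 members, by 1.27 (camera adjusted p = 6.5e-10; 0.571 with an estimated correlation). Markers of other cell types were higher with them: collagens and matrix genes in 24 of 25 members, by 1.72 (6.1e-09), fibroblast markers by 1.44 (0.00137) and blood endothelial markers by 1.30 (0.0124). Cell cycle genes were higher in 29 of 29 members, by 1.27 (5.3e-11), and proliferation markers by 1.62 (9.6e-06). Mitochondrial genome genes were lower by -0.25 (0.0124), and each of these had 0.571 with an estimated correlation. In basal/myoepithelial-like cells, cell cycle genes were higher in 25 of 25 members, by 2.48 (camera adjusted p = 2.7e-18; 0.402 estimated; fry 0.0414), with Top2a at 135 and 155 CPM against 3.63, 6.39 and 11.6, while the immediate-early gene Egr1 was lower by -2.63 ± 0.22 (SE). With them, immediate-early and dissociation genes were lower by -1.24 (camera adjusted p = 1.2e-12; 0.611 estimated) and mitochondrial genome genes by -0.79 (9.3e-13; 0.611), while macrophage markers were lower by -2.17 (0.0426; 0.680) and fibroblast markers higher by 1.15 (0.0407; 0.700). In fibroblast-like cells, Hmox1, heme oxygenase 1, had 833 and 800 CPM against 157, 136 and 159 (log2 2.44 ± 0.14 SE). Immediate-early and dissociation genes were lower there by -0.58 (camera adjusted p = 0.0299, and 0.822 estimated). Epithelial adhesion genes were higher by 1.17 (5.9e-06, and 0.796). Pericyte/vascular smooth muscle markers were higher by 0.70 (0.0299, and 0.796) and NK/innate lymphoid markers by 1.88 (0.0323, and 0.796).

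Handling or a library batch acting on all cells alike should move the same genes in every class. Of the genes called in hormone-sensing luminal-like cells and tested in fibroblast-like cells, 7.54% were called there in the same direction. Their median log2 change was 0.24 in fibroblast-like against 1.41 in hormone-sensing luminal-like cells, a comparison added after the values were seen. These genes were picked by their change in hormone-sensing luminal-like cells, which raises it there, and a shared change can go uncalled in another class. The values therefore cannot decide whether such a batch is the whole cause. A part shared by the classes stays open: collagens and matrix genes passed as higher in all 4 classes (camera adjusted p = 9.6e-06, 6.1e-09, 0.0107 and 2.2e-04; 0.608, 0.571, 0.680 and 0.796 estimated), immediate-early and dissociation genes and mitochondrial genome genes each passed as lower in 3, and 70.35% of the genes called in hormone-sensing luminal-like cells had the same sign in fibroblast-like cells, as did 88.46% of the genes called in luminal progenitor-like and 91.82% of those called in basal/myoepithelial-like cells when read in hormone-sensing luminal-like cells. Over all pairs of these classes the share with the same sign ran from 60.69% to 91.82%. The lowest was for genes called in hormone-sensing luminal-like and read in basal/myoepithelial-like cells. A hormonal state shared by both animals is a candidate explanation that these values cannot decide. Ovarian hormone response genes were lower in hormone-sensing luminal-like cells, by -0.79 (camera adjusted p = 0.0124, and 0.571 with an estimated correlation). They were also lower in luminal progenitor-like cells, by -0.37 (0.0141, and 0.578). They did not differ detectably in basal/myoepithelial-like (0.684) or fibroblast-like cells (0.896). Differences between classes were not tested, and other lists, such as cell cycle genes (5.3e-11), differed more strongly in hormone-sensing luminal-like cells. Age, cycle stage and tissue collection stay open, as no label gives them.

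MHC class I genes were lower in knockout-labelled libraries in several classes. H2-Q7 had 916.9 CPM or more in NK/innate lymphoid-like cells of each of these libraries. However, H2-Q7 and H2-Q6 counts cannot be separated, so reads of H2-Q6 could supply that level. The value therefore cannot decide whether the reference misses a form of H2-Q7 in these libraries. Leukocyte RNA as the whole cause is argued against in fibroblast-like cells, where pan-leukocyte genes supplied at most 3.54% of the needed drop over 6 pairs of libraries. In luminal progenitor-like cells they supplied 0.368% to 3.12% in 5 pairs, but 89.5% for KO2 against WT2, whose sums of 3355 and 3413 CPM leave almost no drop to explain, so a bound of 20% in all 6 pairs was missed there, and 1 pair reached 34.3% in basal/myoepithelial-like cells. In fibroblast-like, macrophage-like and monocyte-like cells both WT libraries lay above all knockout-labelled ones, by at least 1.62 times the SD of the latter. Only these classes had a gap above that SD, and they were set for this test after the values were seen. They therefore cannot decide whether a high value in WT1 alone explains the pattern. Among the other classes the gap ran from 0.611 times the SD in dendritic cell-like to -0.709 times in hormone-sensing luminal-like cells. In luminal progenitor-like cells a high value in WT1 alone cannot be told apart from a genotype difference, with a gap of 0.117 log2 units against an SD of 0.645. In hormone-sensing luminal-like cells WT1 lay below KO2, at 6.78 against 7.20; genotype and strain background, which is not given in the sources used here, stay open and untested.

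A biological hypothesis is that less interferon gamma from fewer NK cells lowers these genes, and it stays open. The mean of genes induced mainly by interferon gamma was below that of type I interferon genes in 8 of 10 classes, the number asked for, but both below it and below 0 in 7, a stricter count added after the former was seen. In monocyte-like and dendritic cell-like cells the type I mean was higher in the knockout-labelled libraries, by 1.92 and 0.99, with gamma means of 0.019 and -0.69. In B cell-like cells the gamma and type I means were nearly equal, at -0.171 and -0.159, the latter over 3 genes. All classes come from the same mice, so they are not separate observations. The gamma list was written after Cxcl9 was seen and shares genes with the MHC class I and interferon lists. Ifng (chromosome 10 at 118441046 to 118445892) had 1.34, 4.87 and 3.25 CPM in KO1, KO2 and KO3 against 8.42 and 9.22 in WT1 and WT2 over all cells used, and 130, 219 and 153 against 200 and 145 within NK/innate lymphoid-like cells. Within T cell-like cells it had 4.28, 31.0 and 30.5 against 173 and 42.4 (log2 -2.63, edgeR adjusted p = 0.9996), but a cluster led by Lef1 and Ccr7 held 298 of the 390 such cells of KO1 and 34 of the 200 of WT1, and in the other cluster it had 18.8, 43.9 and 32.5 against 212 and 60.3; the lower NK/innate lymphoid-like share had an exact permutation p of 0.1, the smallest possible.

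2210407C18Rik, an unnamed gene model on mm10 chromosome 11 at 58608204 to 58616075, minus strand, had 1, 0 and 0 UMIs in the cells used from KO1, KO2 and KO3 and 77 and 260 in those from WT1 and WT2. In hormone-sensing luminal-like cells it had 0, 0 and 0 against 38 and 246 UMIs, and in luminal progenitor-like cells 0, 0 and 0 against 34 and 10. Whether both genotypes share a strain background is not given in the sources used here, so these counts cannot be tied to Frmd3.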
